A study of Homo sapiens with 30 samples.

How the data were processed

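Total RNA of A549 cells was labelled with Cy3 and hybridized to 1-colour Agilent arrays. Per the file headers, Agilent Feature Extraction 10.7.3.1 gave for each spot a processed signal in units of intensity, after background subtraction and detrending within the array and with no normalization between arrays. The same software gave the mean spot brightness and the median local background as intensities (per the file headers), and marks of 0 or 1 for saturated, outlying and well measured spots. The deposited table of the authors holds log2 signals for 30 arrays, and its columns share their quantiles within 3 sets, control 1 with propanal to hexanal, control 2 with heptanal and octanal, and control 3 with nonanal. It had r of 0.993 to 1.00 across probes with the log2 processed signal of the same array. A scanner file was used for 29 of the arrays. The scanner file of butanal replicate 2 was not used here, so butanal had n = 2 except where the authors' values are named.

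Each array had 44495 spots, 43118 of them for 34127 probes other than controls. Spots the software marked as outliers were left out and the rest averaged per probe. The 90 probes with no spot left on 1 or more arrays were dropped. Log2 processed signals were shifted by each array's 75th percentile. Gene names came from a table of RefSeq genes, 24827 probes by accession, 1276 by symbol and 500 by an older symbol, and 7524 kept their own name from the files. Probes well above background on every array of at least 1 group were kept (23978). Each gene was represented by its brightest probe, which gave 19219 genes, 15507 of them with a symbol in the table and 3950 with more than 1 probe. In 17 genes for propanal, 111 genes for butanal, 5 genes for pentanal, 3 genes for hexanal, 1 genes for heptanal, 2 genes for octanal and 0 genes for nonanal probes of the same gene were called in opposite directions. Probe positions are those of the files, on build hg18.

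Groups came from the titles. One model of the 10 group means was fitted to all 29 arrays with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with no covariate. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. The comparisons were each aldehyde minus its own control, the mean of the 7, neighbours that differ by 1 carbon, linear trends over carbons, and a moderated F test of the control sets. Where neighbours had different control sets, the difference of their changes was tested. Where no array of the dimmer group was well above background, a fold was computed from the background limit and is given as at least that value. No fold is given for saturated probes. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over all 189 pairs, and alternatives were a correlation estimated per list and fry. fry tests whether a list moves one way without comparing it with other genes. The 27 lists were NRF2 targets, aldehyde and alcohol metabolism, aryl hydrocarbon receptor targets, cytosolic heat shock, endoplasmic reticulum unfolded protein response, ATF4 targets, p53 targets, DNA replication, mitosis, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and PPAR targets, NF-kB targets and cytokines, interferon-stimulated genes, hypoxia response, metallothioneins, immediate early genes, mesenchymal and TGF-beta genes, epithelial junction genes, alveolar type II and surfactant genes, replication-dependent histones, mitochondrial respiratory chain, cytosolic ribosomal proteins, autophagy and lysosome, leukocyte markers, fibroblast markers and endothelial markers. They held 10 to 37 genes, of which 5 to 36 were measured.

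The gene lists, a panel of 30 genes, the comparisons and the main alternatives were fixed before the data were examined. The genes named in the text follow a rule fixed then as well. It takes the panel, the 6 highest and 6 lowest called changes per aldehyde among genes with a symbol and a signal well above background, and up to 4 members with the smallest adjusted p of each list that passed. It also takes the 10 highest and 10 lowest mean changes with 1 sign in all 7 aldehydes, the 5 highest and 5 lowest of each neighbour comparison and trend, and the 5 genes with the smallest adjusted p between control sets. Names were taken from near the top of each order or, within the panel, chosen after their values were seen, and in the mean and the trends genes at background in a control or an aldehyde were passed over. RIMS4, ROR2 and THY1 are named because a count of 4 held them. Some genes that the rule takes are not reported here.

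Values for all arrays were simulated as each gene's mean over all arrays plus independent noise of its residual SD. The fit was tested on them, with 200 of 19219 genes changed in propanal. It recovered 53.7% of genes changed by 0.5 log2, 76.1% of those changed by 1 and 87.9% of those changed by 2, and called 10 unchanged genes. With nothing changed, 0 of 189 list tests passed with camera. The noise held no slide or scan batch effect, so these numbers do not give the error rates where such effects exist. Simulated unchanged groups that shared the controls gave the values expected from sharing. Scan dates in the files split the arrays into 2 batches, and the array numbers gave 10 slides. The first arrays of control 3 and nonanal lay on 1 slide read by a second scanner, with no saturated probe. Slide and group largely coincide in the second batch, so the slide effect and the group effect are only in part separable.

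Alternatives tried were quantile normalization, a median shift, a normexp background correction with an offset of 50.0, no filter on dim probes, probes well above background on every array, the mean of all probes of a gene, the authors' values, a minimum fold of 1.5, the groups of the control set concerned alone, the replicate number, scan batch or slide as a block, eBayes with trend and robust, and leaving out each array in turn. Chosen after seeing the data were normexp with outlying backgrounds replaced, the slide as a fixed term in every comparison, the scan batch as a fixed term with the slide as a random one, and the second scan batch alone, which holds 1 array of butanal. As a block the slide was a fixed term where a slide held more than 1 group of the comparison, and a random one elsewhere. Arrays were also regrouped at random, 100 times at most, to see how many calls other groupings give, and, also chosen later, within each scan batch. The number of arrays per group limits the precision of each value.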

Results

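Transcripts were measured in A549 cells, a human lung adenocarcinoma line, after 48 h of exposure to 1 of 7 saturated straight-chain aldehydes dissolved in dimethyl sulfoxide (DMSO), from propanal with 3 carbons to nonanal with 9. The labels give each dose as IC20 and no concentration, so the doses of the 7 aldehydes are not known to be equal. Each group had 3 arrays, with 2 of them used here for butanal, and 3 sets of 3 DMSO arrays served as controls. Control 1 belonged to propanal, butanal, pentanal and hexanal, control 2 to heptanal and octanal, and control 3 to nonanal. Between 56.7% and 83.7% of the probes on an array stood well above background, and the small number of arrays limits the precision of every value. Replicate 1 of each group was scanned in a first batch and replicates 2 and 3 in a second one. In the second batch no aldehyde lay on the slide of its own control. Changes against the own control there cannot be told apart from slide effects. In the first batch only propanal and nonanal shared a slide with their own control. The labels do not say whether replicates were separate cultures, so each p-value measures a spread between arrays that is possibly technical. The SD over genes was 0.118 to 0.225 log2 between replicates 2 and 3 of a group, and 0.268 to 0.418 between the scan batches.

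Each aldehyde was compared with its own control set to find the transcripts that changed. Of 19219 genes tested, limma called 4875 genes with propanal (2980 higher, 1895 lower), 7330 genes with butanal (4129 higher, 3201 lower), 3755 genes with pentanal (2222 higher, 1533 lower) and 1350 genes with hexanal (807 higher, 543 lower). It called 1944 genes with heptanal (1101 higher, 843 lower), 1879 genes with octanal (949 higher, 930 lower) and 251 genes with nonanal (173 higher, 78 lower). With the scan batch as a block the counts were 6681 for propanal, 9585 for butanal, 5797 for pentanal, 3596 for hexanal, 4174 for heptanal, 3709 for octanal and 1227 for nonanal, and this fit also called 4875, 7330, 3755, 1350, 1944, 1879 and 251 of the genes above, in the same order. Between 98.7% and 100% of the called genes had the same sign in both scan batches. The calls were made on these same arrays, so neither this nor the overlap with the block fit is independent support. Over all genes, changes in the first and second batch had r of 0.19 for nonanal to 0.69 for butanal. With the median shift the counts from propanal to nonanal were 2497, 5431, 3403, 1725, 1005, 262 and 280. Leaving out 1 array moved the count between 58 and 744 for nonanal and between 796 and 2525 for heptanal. The share of called genes that were higher depended on the scaling. It was 56.3% (42.1% and 26.9%) for butanal in the main scaling (with quantile normalization and with a median shift), 59.2% (43.6% and 26%) for pentanal, 59.8% (32.2% and 15.5%) for hexanal and 56.6% (50.2% and 19%) for heptanal. It was 50.5% (52% and 35.9%) for octanal and 68.9% (28% and 48.6%) for nonanal. For propanal it was 61.1% (55.7% and 59%), so higher genes outnumbered lower ones in each of these scalings. The median shift moved the median of all genes by -0.23 for butanal, -0.22 for pentanal, -0.25 for hexanal, -0.22 for heptanal, -0.13 for octanal and -0.21 for nonanal on the log2 scale, and quantile normalization moved it by -0.14 for butanal.

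**Figure D1:**
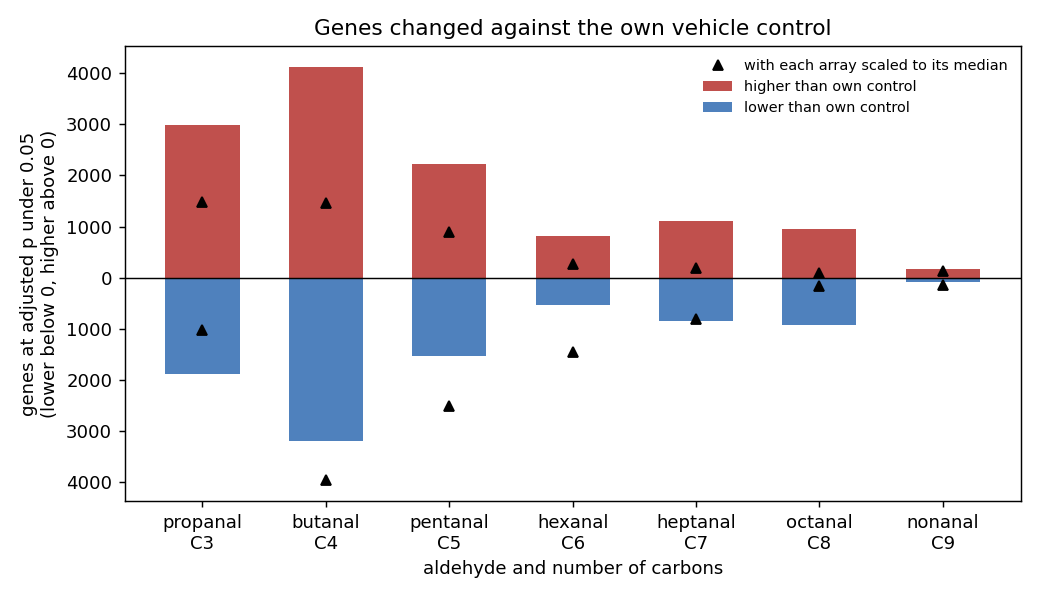
Number of genes at adjusted p under 0.05 that were higher or lower than in the aldehyde's own DMSO control (bars, by aldehyde from 3 to 9 carbons), with triangles for the same counts after scaling each array to its median. Butanal had 4129 higher and 3201 lower genes and nonanal 173 and 78, and with the median scaling lower genes outnumbered higher ones for butanal, pentanal, hexanal, heptanal and octanal and also, by a small margin, for nonanal.

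Lists of genes with a shared function were tested with camera, which compares a list with the other genes. Of 189 pairs of a list and an aldehyde, 82 passed with the preset correlation between genes and 30 of these also with an estimated one. Arrays regrouped at random within the control sets gave a median of 42 passes with the preset and 0 with the estimated correlation, so lists that passed with both come first. These 30 all passed with the scan batch as a block, and their medians kept their sign with quantile normalization and with the median shift. With the slide as a fixed term all 30 kept their direction and 25 passed. Of all 82 calls with the preset correlation 77 kept their direction then and 43 passed. That term compares groups only through slides that they shared, in a chain. Hexanal, for one, was tied to control 1 only by way of propanal, control 3, nonanal, octanal and heptanal. Some ties rest on single arrays of the first batch, as for nonanal with control 3, so the fixed slide term is a weak check. In parentheses after a gene are its log2 change against its own control ± SE (n = 3 arrays per group, 2 for butanal), or a lower bound of its fold change.

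Propanal lowered genes of cell division. The mitosis genes CCNA2 (-1.11 ± 0.050), CENPE (-0.81 ± 0.055) and CDK1 (-0.62 ± 0.044) encode cyclin A2, a kinetochore motor and the mitotic kinase, and among the measured mitosis genes 0 of 26 were higher, 25 lower and 1 not called (0 higher and 26 lower adjusted over the list alone). Their median was -0.73 (-0.76 and -0.72 in the first and second scan batch, adjusted p = 1.48e-28, or 6.68e-06 with an estimated correlation). Among DNA replication genes 1 of 30 were higher, 24 lower and 5 not called (1 higher and 27 lower adjusted over the list alone). They included RRM2 (-0.89 ± 0.066) and GINS2 (-0.69 ± 0.054), which supply nucleotides and the replicative helicase (median -0.51, -0.53 and -0.49 by scan batch, adjusted p = 0.00149 with an estimated correlation). Replication-dependent histone genes fell as well, H4C4 (-0.91 ± 0.10) and H3C2 (-1.14 ± 0.15) among them, and 0 of 22 were higher, 17 lower and 5 not called (0 higher and 18 lower adjusted over the list alone, median -0.60, adjusted p = 0.0139 with an estimated correlation).

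Inflammatory genes rose with propanal. The chemokines CCL20 (1.71 ± 0.10) and CXCL1 (1.25 ± 0.073) and the cytokine IL6 (1.59 ± 0.11) were among the NF-kB targets with the smallest adjusted p. Of that list 20 of 26 were higher, 0 lower and 6 not called (22 higher and 0 lower adjusted over the list alone, median 0.93, 0.96 and 0.94 by scan batch, adjusted p = 3.42e-04 with an estimated correlation). Of the p53 targets, 19 of 25 were higher, 0 lower and 6 not called (19 higher and 0 lower adjusted over the list alone, median 0.53, 0.53 and 0.56 by scan batch, adjusted p = 3.42e-04 with an estimated correlation). Among them GADD45A (1.03 ± 0.10), SESN1 (0.80 ± 0.078) and BTG2 (0.88 ± 0.087) are growth arrest and stress genes. Aryl hydrocarbon receptor targets, which include detoxifying enzymes, had 5 of 8 members higher and 0 lower (5 higher and 0 lower adjusted over the list alone, adjusted p = 0.023 with an estimated correlation), with TIPARP (1.16 ± 0.11), UGT1A6 (0.51 ± 0.052) and AHRR (0.70 ± 0.12). AHRR turned sign with normexp. Genes listed as fibroblast markers, THY1 (1.78 ± 0.086), LUM (1.76 ± 0.18) and COL1A1 (1.11 ± 0.17) among them, had a median of 0.86 (5 of 8 higher, 5 higher and 0 lower adjusted over the list alone, adjusted p = 0.0133 with an estimated correlation).

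Called rises with propanal included those of GKN2 (at least 8.32-fold), ALOX5 (at least 4.23-fold) and LINC00520 (at least 2.87-fold). GKN2 encodes a secreted gastrokine and ALOX5 the lipoxygenase that starts leukotriene synthesis, and a fold is a lower bound where no control array was well above background. Called falls included those of ERP27 (at least 2.99-fold) and CA9 (-2.48 ± 0.12), where CA9 encodes a carbonic anhydrase induced by hypoxia (probe at chromosome 9, 35667817 to 35669204, hg18). In all, 14 gene lists passed with propanal, 7 of them also with an estimated correlation. Metallothioneins (median 0.54, adjusted p = 4.51e-05, or 0.0761 with an estimated correlation) and NRF2 targets (median -0.16, adjusted p = 0.0118, or 0.142 with an estimated correlation) were among the others.

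Butanal raised chemokines and cytokines. CCL20 (3.77 ± 0.11) (probe at chromosome 2, 228389344 to 228390080, hg18), IL6 (3.09 ± 0.12) and BIRC3 (2.52 ± 0.11), an inhibitor of apoptosis, were among the NF-kB targets with the smallest adjusted p. Of that list 23 of 26 were higher, 1 lower and 2 not called (23 higher and 1 lower adjusted over the list alone). The list median was 1.69, 1.80 and 1.86 by scan batch, at adjusted p = 1.61e-16, or 3.64e-04 with an estimated correlation. Metallothioneins, small proteins that bind zinc and copper, were higher in 9 of 10 members (9 higher and 0 lower adjusted over the list alone), such as MT1H (1.15 ± 0.088) and MT1E (1.25 ± 0.10), with a median of 0.99 (0.99 and 1.06 by scan batch, adjusted p = 0.046 with an estimated correlation). The immediate early transcription factors EGR2 and EGR4 rose at least 12.5-fold and at least 11.4-fold and EGR1 (3.27 ± 0.19) also rose. The list of immediate early genes had a median of 0.64 and 14 higher and 2 lower of 19 members (14 higher and 2 lower adjusted over the list alone, adjusted p = 0.00183, or 0.157 with an estimated correlation). Among ATF4 targets, which respond to amino acid and endoplasmic reticulum stress, MTHFD2 (0.55 ± 0.043) and ATF3 (2.27 ± 0.20) rose and SLC7A11 (-0.81 ± 0.073), the cystine transporter, fell (14 higher and 3 lower of 26, 14 higher and 3 lower adjusted over the list alone, adjusted p = 0.0155, or 0.246 with an estimated correlation). GKN2 rose at least 30.3-fold, and NGFR (5.48 ± 0.37), a neurotrophin receptor, rose as well, while ERP27 (at least 2.77-fold, call lost in 4 of 16 alternatives) fell. In all, 10 gene lists passed with butanal, 2 of them also with an estimated correlation.

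With pentanal, CCL20 (2.51 ± 0.10), IL6 (2.17 ± 0.11) and CXCL8 (2.14 ± 0.12) rose, and of the NF-kB targets 22 of 26 were higher, 0 lower and 4 not called (22 higher and 0 lower adjusted over the list alone, median 1.04, 1.14 and 1.01 by scan batch, adjusted p = 1.81e-04 with an estimated correlation). Interferon-stimulated genes such as HERC5 (0.73 ± 0.054), OASL (1.43 ± 0.14) and ISG15 (0.84 ± 0.10), which act against viruses, were higher in 12 of 24 members and lower in 1 (12 higher and 1 lower adjusted over the list alone). Their median was 0.58, 0.38 and 0.57 by scan batch, at adjusted p = 0.00227 with an estimated correlation, and the list did not pass with the slide as a fixed term (median 0.30, adjusted p = 0.152). Metallothioneins had 9 of 10 members higher (9 higher and 0 lower adjusted over the list alone, median 0.71, adjusted p = 0.0202 with an estimated correlation), with MT1H (0.82 ± 0.078) and MT1E (0.89 ± 0.093). Fibroblast markers had a median of 1.05 with THY1 (2.05 ± 0.086) and LUM (1.44 ± 0.18) (4 of 8 higher, 4 higher and 0 lower adjusted over the list alone, adjusted p = 0.01 with an estimated correlation, and 0.101 with the slide as a fixed term). Some genes of mitosis fell, CCNA2 (-0.38 ± 0.050) and CENPE (-0.34 ± 0.055) among them (8 lower and 0 higher of 26, 0 higher and 10 lower adjusted over the list alone, median -0.16, adjusted p = 0.00894 with an estimated correlation). Hypoxia genes had 10 lower and 2 higher members of 22 (2 higher and 11 lower adjusted over the list alone, median -0.21, adjusted p = 0.0139 with an estimated correlation). CA9 (-1.30 ± 0.12) and PDK1 (-0.51 ± 0.052) fell while HK2 (1.20 ± 0.19), a hexokinase, rose. GKN2 rose at least 16.7-fold and IL1RL1, the receptor of an alarmin cytokine, at least 4.84-fold. In all, 11 gene lists passed with pentanal, 6 of them also with an estimated correlation.

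Some hypoxia genes fell with hexanal. PDK1 (-0.26 ± 0.052), CA12 (-0.35 ± 0.070, call lost in 5 of 17 alternatives) and SLC2A3 (-0.46 ± 0.10, call lost in 4 of 16 alternatives), which encode a pyruvate dehydrogenase kinase, a carbonic anhydrase and a glucose transporter, were the hypoxia genes with the smallest adjusted p. Of that list 1 of 22 were higher, 5 lower and 16 not called (2 higher and 7 lower adjusted over the list alone, median -0.11, -0.084 and -0.12 by scan batch, adjusted p = 4.14e-04, or 0.0042 with an estimated correlation). TXNIP (-0.87 ± 0.22), a glucose-responsive binding partner of thioredoxin, fell, and EGR1 (-0.80 ± 0.17) fell where it had risen with butanal and pentanal. Called rises included those of MYOZ1 (at least 2.46-fold), SIX2 (at least 4.99-fold, call lost in 4 of 16 alternatives) and HLA-DPB1 (3.00 ± 0.57). HLA-DPB1 was well above background on 1 of 3 arrays of control 1, and it reversed with the slide as a fixed term. Leukocyte markers passed with the preset correlation (median 0.85, 0.26 and 0.75 by scan batch, 2 of 14 higher and 0 lower, 6 higher and 0 lower adjusted over the list alone, adjusted p = 0.00471, or 0.161 with an estimated correlation). In all, 10 gene lists passed with hexanal, 1 of them also with an estimated correlation.

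Heptanal and octanal lowered some genes of cell division. CCNA2 (-0.49 ± 0.050) and CDK1 (-0.40 ± 0.044) fell with heptanal and CDK1 (-0.46 ± 0.044) and CCNA2 (-0.51 ± 0.050) with octanal. Of 26 mitosis genes 11 were lower with heptanal and 14 with octanal, and 0 were higher with either (17 and 22 lower adjusted over the list alone). Their medians were -0.26 (-0.20 and -0.29 by scan batch) and -0.27 (-0.21 and -0.29), at adjusted p = 4.94e-04 and 1.98e-04 with an estimated correlation. Histone genes such as H4C1 (-0.64 ± 0.10) with heptanal had medians of -0.39 and -0.35 (10 and 8 of 22 lower, 16 and 16 adjusted over the list alone, adjusted p = 0.00886 and 0.0131 with an estimated correlation). DNA replication genes, led by GINS2 (-0.41 ± 0.054) with heptanal and GINS2 (-0.45 ± 0.054) with octanal, had 9 and 9 of 30 lower (10 and 16 adjusted over the list alone, medians -0.18 and -0.21, adjusted p = 0.0147 and 0.00571 with an estimated correlation). Some hypoxia genes fell with both, and CA9 (-0.72 ± 0.12) and CA9 (-1.07 ± 0.12) had the smallest adjusted p of that list. Its counts were 6 and 6 of 22 lower, 0 and 0 higher and the rest not called (8 and 10 lower and 0 and 1 higher adjusted over the list alone, medians -0.11 and -0.14, adjusted p = 0.00482 and 0.00158 with an estimated correlation).

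The glucose-responsive arrestin genes fell with both aldehydes, ARRDC4 (-1.36 ± 0.38, -3.05 and -0.51 by scan batch, call lost in 7 of 16 alternatives) and TXNIP (-1.10 ± 0.22) with heptanal and ARRDC4 (-1.58 ± 0.38, -3.21 and -0.77 by scan batch) and TXNIP (-1.37 ± 0.22) with octanal. With octanal ARRDC4 lost its call in 3 of 16 alternatives, and both genes turned sign with the normexp background correction. Some cholesterol synthesis genes fell with heptanal, ACAT2 (-0.46 ± 0.065) among them, and the list passed relative to other genes. Of its members 0 of 24 were higher, 4 lower and 20 not called (0 higher and 5 lower adjusted over the list alone, median -0.15, -0.16 and -0.13 by scan batch, adjusted p = 0.0017 with an estimated correlation). With octanal, some ATF4 targets rose, and PSAT1 (0.53 ± 0.054), MTHFD2 (0.31 ± 0.038) and CHAC1 (1.34 ± 0.16) act in serine, folate and glutathione metabolism. The list had 12 of 26 higher and 0 lower (17 higher and 1 lower adjusted over the list alone, median 0.32, 0.30 and 0.27 by scan batch, adjusted p = 0.019 with an estimated correlation). Octanal also raised some genes of lipid use. The transcription factor CREB3L3 (1.35 ± 0.088), the lipid droplet coat protein PLIN2 (0.64 ± 0.070) and the kinase PDK4 (0.98 ± 0.14) led the list of fatty acid oxidation and PPAR targets. Of these, 6 of 25 were higher, 0 lower and 19 not called (7 higher and 0 lower adjusted over the list alone, median 0.16, 0.083 and 0.11 by scan batch, adjusted p = 0.0289 with an estimated correlation). That list did not pass with the slide as a fixed term (adjusted p = 0.172). CYP4A22, of a family that oxidizes fatty acids, rose at least 2.58-fold, with its call lost in 4 of 16 alternatives. CREB3L3 and PLIN2 were not raised by octanal alone. The normalized log2 signal of CREB3L3 was above every array of the own control on every array from propanal to heptanal. With butanal it was -0.51 and -0.46, against -1.93, -2.27 and -2.28 in control 1. That of PLIN2 was above every own control array with propanal, butanal, pentanal and heptanal. Fibroblast markers, led by THY1 (0.85 ± 0.086) and LUM (0.89 ± 0.18, call lost in 6 of 16 alternatives), had 2 of 8 higher with octanal (3 higher and 0 lower adjusted over the list alone, median 0.50, adjusted p = 0.0205 with an estimated correlation, 0.153 with the slide as a fixed term). In all, 13 gene lists passed with heptanal, 5 of them also with an estimated correlation, and 11 gene lists passed with octanal, 7 of them also with an estimated correlation.

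Nonanal lowered some genes of lipid use. PLIN2 (-0.60 ± 0.070), ANGPTL4 (-0.76 ± 0.10), CREB3L3 (-0.58 ± 0.088) and PDK4 (-0.74 ± 0.14) fell, where ANGPTL4 encodes an inhibitor of lipoprotein lipase, and of the fatty acid oxidation and PPAR targets 0 of 25 were higher, 5 lower and 20 not called (0 higher and 9 lower adjusted over the list alone). Their median was -0.12, -0.14 and -0.10 by scan batch, at adjusted p = 1.93e-09, or 9.17e-04 with an estimated correlation. The p53 targets passed towards lower values with 0 members called higher and 0 lower of 25 by limma (0 higher and 0 lower adjusted over the list alone, median -0.057, adjusted p = 0.0443 with an estimated correlation), and did not pass with the slide as a fixed term (adjusted p = 0.194). CFAP73, a gene of cilia, rose at least 3.31-fold and the olfactory receptor gene OR1L3 at least 3.47-fold, and each lost its call in 4 of 15 alternatives. Among the falls, MYZAP (-0.95 ± 0.072) had another probe with a change of the opposite sign and turned sign with normexp. DHRS9 (-0.80 ± 0.12) and FCGBP (-0.79 ± 0.091), which also fell, encode a retinol dehydrogenase and a mucus protein. In all, 13 gene lists passed with nonanal, 2 of them also with an estimated correlation.

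**Figure D2:**
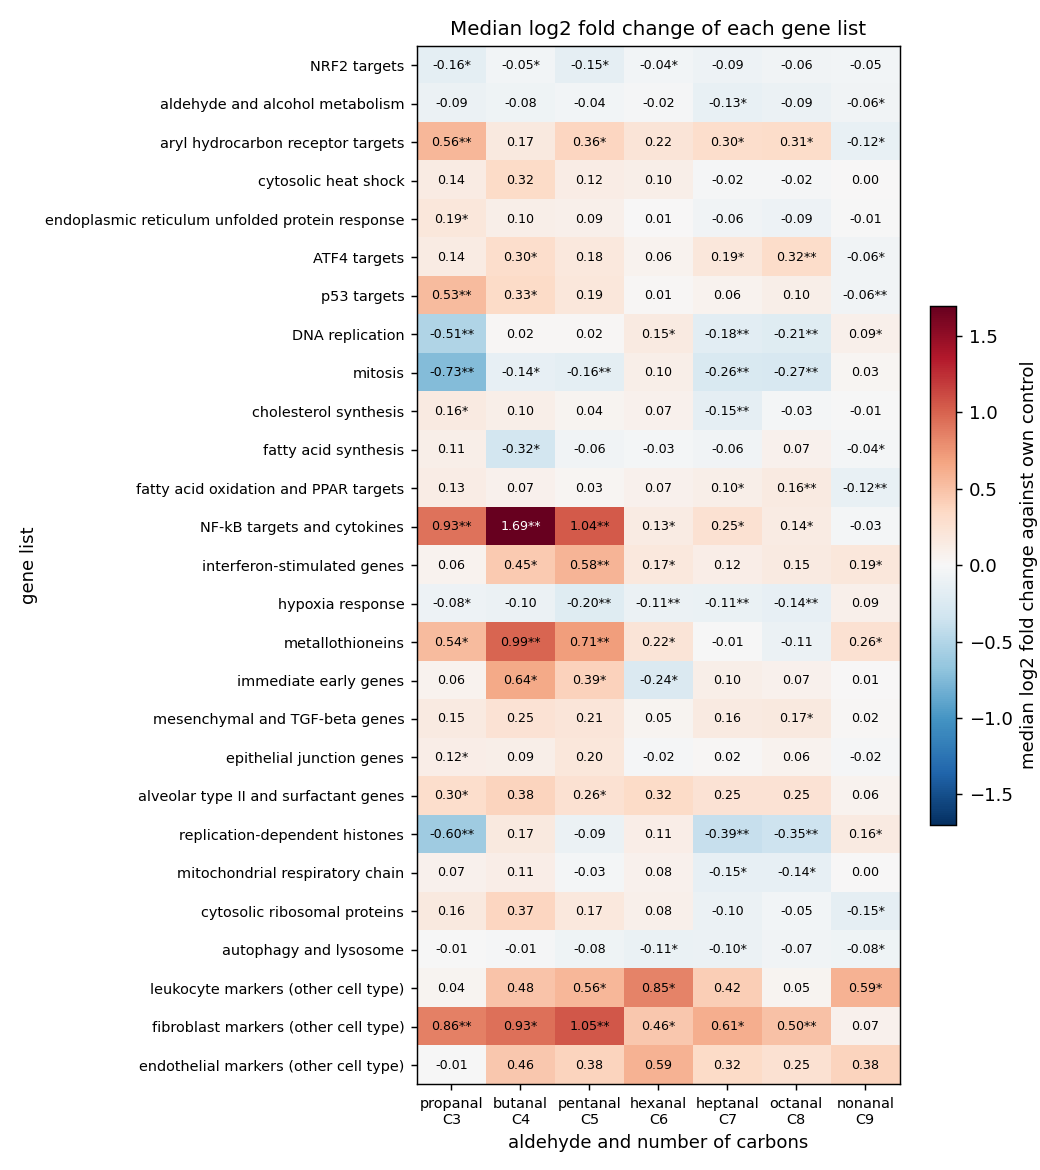
Median log2 change against the own control of the genes in each of 27 lists (vertical) for each of the 7 aldehydes (horizontal), as colour, where 1 asterisk marks a list that passed camera with the preset correlation and 2 asterisks one that passed also with an estimated correlation. The NF-kB list had medians of 0.93, 1.69 and 1.04 with propanal, butanal and pentanal, and each of the 30 medians with 2 asterisks kept its sign with quantile normalization and with the median shift.

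Among single genes fixed for every aldehyde, CYP1A1, a target of the aryl hydrocarbon receptor, rose with propanal (1.40 ± 0.29), butanal (1.90 ± 0.33), pentanal (1.51 ± 0.29), hexanal (1.22 ± 0.29, 0.46 and 1.60 by scan batch), heptanal (1.37 ± 0.29) and octanal (1.07 ± 0.29) but was not called with nonanal (0.10 ± 0.29). The nonanal value averages opposite signs (-1.09 and 0.69 by scan batch), and it was called higher in the second batch alone and lower with the slide as a block. With the slide as a fixed term its sign turned for pentanal, hexanal, heptanal and octanal, and for the last 3 the call was lost in 4 of 16 alternatives each. ALDH3A1, which oxidizes aldehydes to fatty acids, was higher with propanal (0.62 ± 0.10), pentanal (0.37 ± 0.10), heptanal (0.54 ± 0.10) and octanal (0.63 ± 0.10), and for pentanal its sign turned with the slide as a fixed term and its call was lost in 5 of 17 alternatives. Its normalized log2 signal was also higher on the hexanal arrays (5.37, 5.03 and 5.08) than on those of control 1 (4.90, 4.67 and 4.72). HMOX1, the heme oxygenase of the oxidative stress response, rose with propanal (0.60 ± 0.18) and fell with heptanal (-0.67 ± 0.18) and octanal (-0.59 ± 0.18). The NRF2 target NQO1 was not called with propanal (-0.15 ± 0.17) or with butanal (-0.19 ± 0.19), but it was called lower with propanal when the slide was a block. DDIT3, a transcription factor of the unfolded protein response, rose with butanal (1.34 ± 0.19). The cell cycle inhibitor CDKN1A rose with propanal (1.09 ± 0.20) and butanal (1.06 ± 0.23, 1.58 and 0.73 by scan batch). Its normalized log2 signals on the arrays of control 1 were uneven (-2.03, -0.87 and -2.08). The heat shock gene HSPA1A was not called with butanal (-0.068 ± 0.075). AKR1B10, AKR1C1 and ALDH1A1 were saturated, so no fold is given for them. Of the 123 gene values against an own control given in the text, 119 were called.

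**Figure D3:**
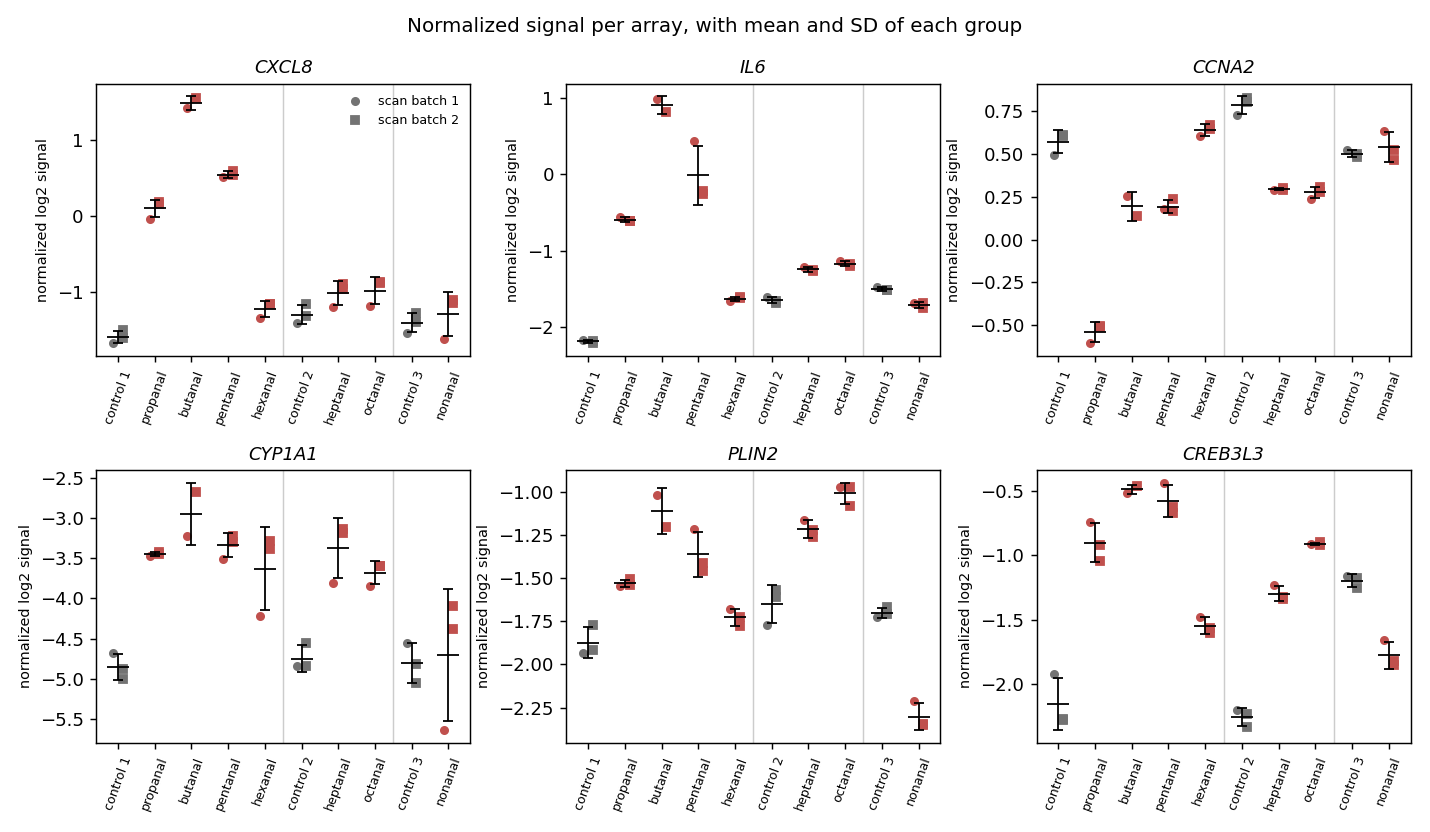
Normalized log2 signal of 6 genes on each array (log2 intensity minus the array's 75th percentile), by group, with circles for the first and squares for the second scan batch and the group mean ± SD. CXCL8 and IL6 stood above control 1 with butanal (IL6 3.09 log2), CCNA2 below it with propanal (-1.11), and PLIN2 above control 2 with octanal (0.64) and below control 3 with nonanal (-0.60).

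The mean over the 7 aldehydes asked what changed on average. The antimicrobial peptide gene CAMP (-0.78 ± 0.22, -1.22 and -0.55 by scan batch) and the histone chaperone gene HIRA (-0.75 ± 0.13, -0.31 and -0.97 by scan batch) fell with 1 sign in all 7, but with the slide as a block the HIRA mean was 0.021, not called. EGR2, EGR4 and GKN2 were at background in control 1, so no mean is given for them. For this mean limma called 6508 genes (4088 higher, 2420 lower, 9083 with the scan batch as a block), of which 62.8% (41.4% and 21.2%) were higher in the main scaling (with quantile normalization and with the median shift, which moved the median of all genes by -0.18 log2). Of the lists, NF-kB targets (median 0.57, adjusted p = 5.06e-16, or 2.07e-04 with an estimated correlation), mitosis genes (median -0.21, adjusted p = 1.46e-14, or 1.76e-04 with an estimated correlation) and interferon-stimulated genes (median 0.31, adjusted p = 4.38e-04, or 0.00899 with an estimated correlation) passed with both correlations. Fibroblast markers (median 0.71, adjusted p = 0.00121, or 0.00899 with an estimated correlation), hypoxia genes (median -0.12, adjusted p = 5.78e-04, or 0.00507 with an estimated correlation) and metallothioneins (median 0.39, adjusted p = 3.29e-05, or 0.0384 with an estimated correlation) did so too. DNA replication genes (median -0.088, adjusted p = 4.56e-05, or 0.0384 with an estimated correlation), NRF2 targets (median -0.091, adjusted p = 2.63e-04, or 0.0384 with an estimated correlation) and genes of aldehyde and alcohol metabolism (median -0.095, adjusted p = 0.00926, or 0.0352 with an estimated correlation) passed towards lower values. Aryl hydrocarbon receptor targets (median 0.28, adjusted p = 0.0108, or 0.0384 with an estimated correlation) and p53 targets (median 0.17, adjusted p = 0.00738, or 0.0384 with an estimated correlation) passed towards higher values relative to other genes, where the p53 median turned to -0.016 with the median shift. ATF4 targets (median 0.13, adjusted p = 0.00251, or 0.152 with an estimated correlation, and a median of -0.049 with the median shift) and histone genes (median -0.13, adjusted p = 8.12e-05, or 0.0653 with an estimated correlation) passed with the preset correlation only. So did leukocyte markers (median 0.49, adjusted p = 0.00926, or 0.198 with an estimated correlation) and surfactant genes (median 0.29, adjusted p = 0.0137, or 0.0579 with an estimated correlation). With the slide as a fixed term the mean passed for NF-kB targets, mitosis, hypoxia and DNA replication genes and leukocyte markers, and for ribosomal protein genes towards higher values (median 0.35, adjusted p = 5.77e-13). The other lists did not pass then, and histone genes turned (median 0.044, adjusted p = 0.908). NRF2 targets turned as well (median 0.048, adjusted p = 0.734), with a median above 0 for each aldehyde except propanal. Interferon-stimulated genes had a median of 0.10 there (adjusted p = 0.711), turned for hexanal (-0.13), heptanal (-0.15) and octanal (-0.022), and passed for none. Single aldehydes went the other way from the mean, with medians of 0.10 with hexanal and 0.034 with nonanal for mitosis, 0.023 with butanal, 0.016 with pentanal, 0.15 with hexanal and 0.086 with nonanal for DNA replication and -0.013 with heptanal and -0.11 with octanal for metallothioneins. Histone genes had 0.17 with butanal, 0.11 with hexanal and 0.16 with nonanal. With nonanal this held for NF-kB targets (-0.033), hypoxia genes (0.088), aryl hydrocarbon receptor targets (-0.12), p53 targets (-0.057) and ATF4 targets (-0.060). The lists that did not pass were those of autophagy and lysosome genes (median -0.050, adjusted p = 0.0615), endothelial markers (median 0.39, adjusted p = 0.0746) and mesenchymal genes (median 0.11, adjusted p = 0.158). The others were genes of the respiratory chain (median 0.0043, adjusted p = 0.189), fatty acid synthesis genes (median -0.070, adjusted p = 0.204) and heat shock genes (median 0.078, adjusted p = 0.208). They also were those of immediate early genes (median 0.20, adjusted p = 0.208), PPAR targets (median 0.042, adjusted p = 0.257), epithelial junction genes (median 0.091, adjusted p = 0.641), ribosomal protein genes (median 0.068, adjusted p = 0.868), genes of the unfolded protein response (median 0.047, adjusted p = 0.879) and cholesterol synthesis genes (median 0.037, adjusted p = 0.89). For the respiratory chain, the ribosomal proteins and the unfolded protein response the test pointed down while the median was above 0.

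limma called 4 genes higher and 0 lower with each of the 7 aldehydes, where independent comparisons with the same numbers of calls would share 7.9e-05 and 6.1e-06. In 20 sets of simulated unchanged groups that shared the controls as here, at most 0 genes were shared and at most 1 call was made. These sets held no slide or scan batch effect. A control set of 3 arrays cannot be split into parts of 2 or more. Among the shared genes were RIMS4 (0.88 ± 0.089 with propanal and 0.85 ± 0.089 with nonanal), ROR2 and THY1. RIMS4 rose more than this with butanal and pentanal and less with hexanal, heptanal and octanal. ROR2, a receptor of the Wnt pathway, rose by 1.27 ± 0.14 with butanal, but its sign turned for hexanal and nonanal with quantile normalization. Its call was lost in 4 of 16 alternatives for butanal, 7 of 16 for hexanal and 5 of 15 for nonanal. THY1, a surface glycoprotein, rose by 2.09 ± 0.10 with butanal and its sign turned for nonanal with quantile normalization, where 7 of 15 alternatives lost its call. With nonanal ROR2 was well above background on 1 of 3 arrays and THY1 on 2 of 3, and neither on any array of control 3. No fold can be stated for them there, and both calls with nonanal are of genes near background. With the scan batch as a block 18 genes were shared, and with quantile normalization or the median shift 1. At least 5 of the 7 aldehydes shared 346 higher and 116 lower genes.

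Aldehydes that differ by 1 carbon were compared to ask whether chain length changed the response. The cytokine genes IL6 (1.5 ± 0.12) and CXCL8 (1.39 ± 0.13) were higher with butanal than with propanal, as was ATF3 (2.23 ± 0.20), a stress transcription factor. EGR4 was at least 3.42 log2 and IL1RL1 at least 2.74 log2 higher with butanal, and LINC00304 (-2.17 ± 0.37, -3.20 and -1.12 by scan batch), well above background on 1 of 2 butanal arrays, was lower. Between butanal and propanal limma called 5890 genes (3051 higher, 2839 lower, 8902 with the scan batch as a block), of which 51.8% (38.8% and 23.1%) were higher in the main scaling (with quantile normalization and with the median shift, which moved the median by -0.11 and -0.21). From butanal to pentanal the same genes fell, IL6 (-0.92 ± 0.12), CXCL8 (-0.94 ± 0.13) and ATF3 (-0.88 ± 0.20, -0.39 and -1.06 by scan batch), while SLC7A11 (0.55 ± 0.073) rose, and limma called 3089 genes (1677 higher, 1412 lower, 5329 with the scan batch as a block), of which 54.3% (63.7% and 64.1%) were higher. PAGE4 was at least 5.91-fold lower with pentanal. From pentanal to hexanal IL6 (-1.61 ± 0.11) and CXCL8 (-1.77 ± 0.12) fell again, GKN2 (-3.15 ± 0.48) fell with NGFR (-2.94 ± 0.33), and limma called 2207 genes (863 higher, 1344 lower, 3832 with the scan batch as a block), of which 39.1% (40.6% and 27.2%) were higher. Of the 30 panel genes, 8 higher and 6 lower were called from propanal to butanal, 4 higher and 8 lower from butanal to pentanal and 0 higher and 10 lower from pentanal to hexanal.

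Heptanal and hexanal had different control sets, so their changes were compared. CPT1A (0.44 ± 0.11, call lost in 4 of 15 alternatives), which carries fatty acids into mitochondria, was the panel gene called. Among other genes ARHGAP31 (2.20 ± 0.62, 3.27 and 1.67 by scan batch, call lost in 7 of 14 alternatives) was higher and SNORA62 (-1.71 ± 0.19) lower with heptanal. For this pair limma called 960 genes (493 higher, 467 lower, 2879 with the scan batch as a block), of which 51.4% were higher in the main scaling and 66.8% with quantile normalization. The median shift left 1. Between heptanal and octanal limma called 4 genes (688 at unadjusted p under 0.05, 22 with the scan batch as a block and 0 with the median shift). LTK, a receptor tyrosine kinase, rose by 1.00 ± 0.13, and AKAP9 (-0.41 ± 0.064, call lost in 6 of 16 alternatives), CENPE (-0.37 ± 0.055, call lost in 5 of 16 alternatives) and TRIP11 (-0.31 ± 0.054, call lost in 6 of 16 alternatives), which act at the centrosome, the kinetochore and the Golgi, fell. The 30 panel genes had 0 higher and 0 lower, and their 95% intervals reached 0.91 log2 at most. Of the fatty acid oxidation and PPAR targets, 9 of 25 were lower with nonanal than with octanal and 0 higher (median -0.32). PLIN2 (-1.24 ± 0.10) and CPT1A (-0.80 ± 0.11) and the droplet protein PLIN4 (-2.44 ± 0.21) were lower with nonanal. So were CREB3L3 (-1.93 ± 0.13) and DHRS9 (-2.52 ± 0.17), while ARRDC4 (2.30 ± 0.54, 3.59 and 1.65 by scan batch, call lost in 4 of 14 alternatives) was higher. Between nonanal and octanal limma called 1381 genes (628 higher, 753 lower, 2933 with the scan batch as a block and 169 with the median shift), of which 45.5% (36.3% and 16%) were higher in the main scaling (with quantile normalization and with the median shift). The 30 panel genes had 1 higher and 7 lower.

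A linear trend with chain length was fitted over propanal to hexanal, which share control 1, and over all 7 aldehydes relative to their own controls. Slopes per carbon from propanal to hexanal were negative for CDKN1A (-0.53 ± 0.065), CXCL8 (-0.49 ± 0.038), IL6 (-0.40 ± 0.034) and NGFR (-1.02 ± 0.11). For CXCL8, IL6 and NGFR they do not stand for a steady fall, since all 3 were higher with butanal than with propanal (NGFR at 5.48 ± 0.37 and 3.08 ± 0.33). CDKN1A was about level between propanal and butanal (1.09 and 1.06 against control 1). Over these 4 aldehydes limma called 6058 genes with this trend (3334 with a positive slope, 2724 with a negative one, 8439 with the scan batch as a block), and 90.2% had the same sign in both scan batches. 55% (46.5% and 32%) of them had a positive slope in the main scaling (with quantile normalization and with the median shift). From propanal to nonanal the slopes of NGFR (-0.84 ± 0.077), CXCL8 (-0.43 ± 0.028) and IL6 (-0.44 ± 0.025) were negative, with the same peak at butanal. Over all 7 limma called 4610 genes (2019 with a positive slope, 2591 with a negative one, 6895 with the scan batch as a block), of which 43.8% (48.4% and 30.5%) had a positive slope.

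Profiles of log2 change were correlated across genes, which are not independent replicates, to ask how alike the aldehydes were. The 14 pairs of aldehydes with different control sets had a median r of 0.432 (-0.237 for propanal with nonanal to 0.733 for hexanal with heptanal), where unchanged groups simulated against the same controls gave 8e-04. With quantile normalization it was 0.243, and with normexp it turned to -0.0901, or 0.242 with outlying backgrounds replaced. The simulation held no slide or scan batch effect, while controls 1 and 2 of the second scan batch lay on 1 slide, as did hexanal and heptanal, so shared slides are not excluded as a source of it. The median covariance was 0.0784, against 5.9e-05 simulated. The 7 pairs that share a control set had a median r of 0.55 (0.0421 for propanal with hexanal to 0.851 for heptanal with octanal), and simulated unchanged groups gave 0.5 from the shared arrays alone. Their median covariance was 0.12, against 0.035 simulated. Between the scan batches, the same aldehyde had a median r of 0.474 (0.185 to 0.691) and different aldehydes 0.207 (-0.075 to 0.577).

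The 3 control sets held the same vehicle, and they were compared to measure how far experiments differed. The neurotensin gene NTS had normalized log2 signals of 4.16 ± 0.0482, 3.88 ± 0.0737 and 1.22 ± 0.137 in controls 1, 2 and 3 (SD, n = 3). Likewise ATL1 (-1.79 ± 0.154, -1.63 ± 0.00444 and -3.87 ± 0.095) and THY1 (-4.04 ± 0.0533, -3.81 ± 0.044 and -6.39 ± 0.19) were lower in control 3, and FCGBP (1.01 ± 0.0327, 0.39 ± 0.113 and 3.09 ± 0.111) was higher. The F test of limma called 6054 genes, 1843 of them by at least 1.5-fold between 2 of the sets, and 9052 with the scan batch as a block. The comparison of each aldehyde with its own control set had been fixed before the data were examined.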

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

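The test of the level in control 3 was chosen only after its result was seen. The results here are effects of neighbouring aldehydes, 1 carbon apart, whose difference passed limma's test of the difference itself. Butanal and propanal differed in 5890 genes, and butanal was higher for ATF3 (2.23 ± 0.20), CXCL8 (1.39 ± 0.13) and IL6 (1.5 ± 0.12), by at least 3.42 log2 for EGR4 and at least 2.74 log2 for IL1RL1, and lower for LINC00304 (-2.17 ± 0.37, -3.20 and -1.12 by scan batch). Pentanal and butanal differed in 3089, with ATF3 (-0.88 ± 0.20, -0.39 and -1.06 by scan batch), CXCL8 (-0.94 ± 0.13) and IL6 (-0.92 ± 0.12) and PAGE4 (-2.56 log2 or below) lower with pentanal and SLC7A11 (0.55 ± 0.073) higher. Hexanal and pentanal differed in 2207, with GKN2 (-3.15 ± 0.48), NGFR (-2.94 ± 0.33), CXCL8 (-1.77 ± 0.12) and IL6 (-1.61 ± 0.11) lower with hexanal. Heptanal and hexanal differed in 960, or 1 with the median shift, with ARHGAP31 (2.20 ± 0.62, 3.27 and 1.67 by scan batch, call lost in 7 of 14 alternatives) and CPT1A (0.44 ± 0.11, call lost in 4 of 15 alternatives) and SNORA62 (-1.71 ± 0.19). Octanal and heptanal differed in 4, which were LTK (1.00 ± 0.13), AKAP9 (-0.41 ± 0.064, call lost in 6 of 16 alternatives), CENPE (-0.37 ± 0.055, call lost in 5 of 16 alternatives) and TRIP11 (-0.31 ± 0.054, call lost in 6 of 16 alternatives). Nonanal and octanal differed in 1381, with ARRDC4 (2.30 ± 0.54, 3.59 and 1.65 by scan batch, call lost in 4 of 14 alternatives) higher and DHRS9 (-2.52 ± 0.17), PLIN4 (-2.44 ± 0.21), CREB3L3 (-1.93 ± 0.13), PLIN2 (-1.24 ± 0.10) and CPT1A (-0.80 ± 0.11) lower with nonanal. With the median shift the counts of these pairs were 4219, 571, 836, 1, 0 and 169, in the same order. The labels give no concentrations, so in a difference between neighbours chain length cannot be told apart from dose.

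Of the genes of lipid use, PDK4, ANGPTL4, PLIN2 and CREB3L3 fell with nonanal and rose with octanal, and over the list the difference had a median of -0.32 with 9 of 25 members called lower and 0 higher. PLIN2 and CREB3L3 also stood above their own control on every array of propanal, butanal, pentanal and heptanal. A slide effect was tested where octanal and nonanal shared a slide, in the second scan batch, and there 22 members were lower with nonanal, PDK4 at -1.30 and PLIN2 at -1.32 log2. The list median of -0.115 (SD 0.492 over members) was too near 0 to exclude a slide effect for the list as a whole. A higher level of these genes in control 3 stays open too, since nonanal against controls 1 and 2 had a list median of -0.0573 (SD 0.33). Single genes differed here, as nonanal was below controls 1 and 2 for ANGPTL4 (-1.11, control 3 at -0.34) and PLIN2 (-0.55, 0.062), while control 3 was higher for PDK4 (0.43, nonanal at -0.32) and CREB3L3 (1.01, 0.42).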

How the results depend on the processing

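Chosen only after the data were seen were the tests with outlying backgrounds replaced, with the slide as a fixed term throughout, with the scan batch fixed and the slide random, and with the second scan batch alone. A count stayed the same here when it was within 1.5 times the main count, and where no cause is named, the cause was not tested. The named genes mostly stayed called. Of 160 gene values in the text, 6 of 160 lost their call with quantile normalization, 21 of 160 with the median shift, 4 of 160 with the authors' values, 0 of 160 with the scan batch as a block and 0 of 160 with the replicate number as a block. Without a filter 8 of 160 lost it, among genes well above background on every array 0 of 102, with all passing probes averaged 3 of 160, with trend and robust 2 of 160, with the own control set alone 14 of 146, with the second scan batch alone 5 of 160 and with a fold of at least 1.5 32 of 160. With the slide as a block 14 of 160 lost it, with the slide fixed throughout 28 of 85, with the scan batch fixed and the slide random 9 of 160, with normexp 83 of 160 and with outlying backgrounds replaced 25 of 160. The 85 values are those of comparisons where the slide block was a random term, so the 2 slide settings cover different sets of values. Over all single arrays left out, 87 of 1108 values lost their call and 0 turned. Calls were gained with the slide as a block (1, NQO1 with propanal), with the scan batch fixed and the slide random (1, the same) and with the second scan batch alone (2, NQO1 from 1 array of butanal and CYP1A1 with nonanal).

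Some genes turned sign. With quantile normalization these were ROR2 with hexanal (-0.010), ROR2 with nonanal (-0.13) and THY1 with nonanal (-0.35). With the authors' values they were ROR2 with hexanal (-0.012), ROR2 with nonanal (-0.10) and THY1 with nonanal (-0.31). With normexp they were ROR2 with hexanal (-0.13), MYZAP with nonanal (0.083), ARRDC4 with octanal (0.60), TXNIP with octanal (0.53) and AHRR with propanal (-0.018), and with outlying backgrounds replaced THY1 with nonanal (-0.026). With the slide as a block they were HIRA with mean of 7 aldehydes (0.021) and CYP1A1 with nonanal (-1.09). With the slide fixed throughout they were CYP1A1 with heptanal (-0.66), CYP1A1 with hexanal (-0.73), HLA-DPB1 with hexanal (-0.65), ROR2 with hexanal (-0.23), CYP1A1 with octanal (-0.70), ALDH3A1 with pentanal (-0.10) and CYP1A1 with pentanal (-0.012).

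Scaling moved counts of called genes. With the median shift they became 2497 for propanal, 1005 for heptanal, 262 for octanal, 571 for pentanal minus butanal, 836 for hexanal minus pentanal, 1 for heptanal minus hexanal, 0 for octanal minus heptanal, 169 for nonanal minus octanal, 1909 for the trend to nonanal, 2784 for the control sets and 1 for the genes shared by all 7. Quantile normalization gave 1 for the genes shared by all 7 and 0.243 for the correlation between aldehydes, and its other counts stayed the same, as did those of the mean of all probes. The authors' values, with the third butanal array, gave 426 for nonanal, 2 for the genes shared by all 7 and 0.247 for the correlation between aldehydes. Normexp gave 1478 for propanal, 2727 for butanal, 728 for pentanal, 4 for hexanal, 100 for heptanal, 770 for octanal, 6 for nonanal, 1632 for the mean of 7, 1549 for butanal minus propanal, 376 for pentanal minus butanal, 265 for hexanal minus pentanal, 6 for heptanal minus hexanal, 0 for octanal minus heptanal, 89 for nonanal minus octanal, 1265 for the trend to hexanal, 2335 for the trend to nonanal, 1430 for the control sets, 0 for the genes shared by all 7 and -0.0901 for the correlation between aldehydes. Between 0 and 11 spots per array lay over 100 below their local background, and such outlying backgrounds entered the fit of this correction. With those replaced the counts were 926 for heptanal, 1065 for octanal, 48 for nonanal, 382 for heptanal minus hexanal, 1 for octanal minus heptanal, 4030 for the trend to hexanal, 0 for the genes shared by all 7 and 0.242 for the correlation between aldehydes.

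The filter and the threshold mattered as well. With no filter, where more genes share the adjustment, the counts were 852 for hexanal, 98 for nonanal, 585 for heptanal minus hexanal and 1 for the genes shared by all 7. Genes well above background on every array gave 100 for nonanal. A fold of at least 1.5, which removes small changes by construction, gave 1633 for propanal, 3084 for butanal, 1238 for pentanal, 426 for hexanal, 475 for heptanal, 281 for octanal, 141 for nonanal, 1325 for the mean of 7, 2085 for butanal minus propanal, 574 for pentanal minus butanal, 710 for hexanal minus pentanal, 126 for heptanal minus hexanal, 1 for octanal minus heptanal, 435 for nonanal minus octanal, 311 for the trend to hexanal, 28 for the trend to nonanal, 1843 for the control sets and 1 for the genes shared by all 7. Trend and robust gave 2 for the genes shared by all 7. With the groups of the own control set alone, which leaves fewer arrays to estimate the spread, the counts were 844 for hexanal, 990 for heptanal, 1055 for octanal, 0 for octanal minus heptanal and 49 for nonanal. Of the list tests 30 passed with an estimated correlation and 127 with fry.

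Blocks mostly raised the counts. With the scan batch as a block they were 5797 for pentanal, 3596 for hexanal, 4174 for heptanal, 3709 for octanal, 1227 for nonanal, 8902 for butanal minus propanal, 5329 for pentanal minus butanal, 3832 for hexanal minus pentanal, 2879 for heptanal minus hexanal, 22 for octanal minus heptanal, 2933 for nonanal minus octanal and 18 for the genes shared by all 7. With the replicate number as a block, a pairing that the labels do not state, they were 5705 for pentanal, 3449 for hexanal, 4046 for heptanal, 3620 for octanal, 1066 for nonanal, 5218 for pentanal minus butanal, 3761 for hexanal minus pentanal, 2846 for heptanal minus hexanal, 24 for octanal minus heptanal, 2909 for nonanal minus octanal and 16 for the genes shared by all 7. In 89 of 126 pairs of arrays with the same number in different groups, deviations from the group means had r above 0.1 (median 0.24, -0.26 to 0.79), but the arrays with number 1 also share the first scan batch, so this does not tell a pairing from a batch. With the slide as a block the counts were 8161 for propanal, 2574 for nonanal, 2801 for the mean of 7, 6296 for pentanal minus butanal, 5882 for hexanal minus pentanal, 5900 for heptanal minus hexanal, 887 for octanal minus heptanal, 3971 for nonanal minus octanal, 3348 for the trend to hexanal, 7339 for the trend to nonanal, 9330 for the control sets, 171 for the genes shared by all 7, 0.673 for the correlation between aldehydes, 511 for hexanal and 3279 for octanal. The correlation within a slide was 0.818, or 0.731 with the scan batch fixed. With the scan batch fixed and the slide random they were 7857 for propanal, 871 for hexanal, 3470 for octanal, 2092 for nonanal, 6786 for pentanal minus butanal, 5527 for hexanal minus pentanal, 5887 for heptanal minus hexanal, 306 for octanal minus heptanal, 4632 for nonanal minus octanal, 7698 for the trend to nonanal, 9410 for the control sets and 12 for the genes shared by all 7. With the slide fixed throughout they were 4678 for butanal and 3153 for octanal. The second scan batch alone, which holds 2 arrays per group, 1 for butanal, and no spread between batches, gave 11409 for propanal, 12762 for butanal, 10666 for pentanal, 9939 for hexanal, 10450 for heptanal, 8259 for octanal, 8192 for nonanal, 13105 for the mean of 7, 12033 for butanal minus propanal, 7347 for pentanal minus butanal, 7238 for hexanal minus pentanal, 5856 for heptanal minus hexanal, 2327 for octanal minus heptanal, 8042 for nonanal minus octanal, 12831 for the trend to hexanal, 11316 for the trend to nonanal, 13742 for the control sets and 395 for the genes shared by all 7.

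Leaving out 1 array moved some counts by more than 1.5 times, each given here for every array that did so. Hexanal ranged from 488 without control 1 replicate 2 to 2386 without hexanal replicate 1, with 522 without control 1 replicate 3, 512 without hexanal replicate 2 and 489 without hexanal replicate 3. Heptanal ranged from 796 without heptanal replicate 2 to 2525 without heptanal replicate 1, with 1124 without control 2 replicate 2, 1100 without control 2 replicate 3 and 831 without heptanal replicate 3. Octanal ranged from 1209 without control 2 replicate 3 to 2134 without nonanal replicate 1, with 1250 without control 2 replicate 2. Nonanal ranged from 58 without control 3 replicate 2 to 744 without control 3 replicate 1, with 167 without control 2 replicate 2, 65 without control 3 replicate 3, 478 without propanal replicate 1, 382 without hexanal replicate 1, 392 without heptanal replicate 1, 603 without nonanal replicate 1, 118 without nonanal replicate 2 and 93 without nonanal replicate 3. Pentanal minus butanal ranged from 850 without butanal replicate 1 to 3381 without control 2 replicate 1. Heptanal minus hexanal ranged from 593 without heptanal replicate 2 to 1167 without control 3 replicate 1, with 614 without control 1 replicate 2, 634 without control 1 replicate 3 and 608 without heptanal replicate 3. Octanal minus heptanal ranged from 1 without heptanal replicate 1 to 5 without control 2 replicate 1, with 1 without heptanal replicate 3, 1 without octanal replicate 2 and 1 without octanal replicate 3. The trend to hexanal ranged from 3788 without propanal replicate 2 to 6875 without hexanal replicate 1, with 3986 without propanal replicate 3 and 4019 without hexanal replicate 2. The genes shared by all 7 ranged from 1 without nonanal replicate 3 to 15 without nonanal replicate 1, with 2 without control 2 replicate 2, 2 without control 2 replicate 3, 10 without control 3 replicate 1, 2 without control 3 replicate 3, 7 without propanal replicate 1, 8 without pentanal replicate 1, 8 without hexanal replicate 1, 2 without hexanal replicate 3, 9 without heptanal replicate 1, 2 without octanal replicate 1 and 2 without nonanal replicate 2. Other counts, the list tests and the correlation between aldehydes (jackknife SE 0.125) stayed the same with each array left out. Without 1 of the butanal arrays the other is assumed to vary like the other groups. Signal over background limits the dim genes. The genes in the lowest 10% of signal had a median change of 0.14 in the first and 0.83 in the second scan batch for hexanal, and a fold is only a lower bound where a group was at background.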

Other observations

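The tests of the regroupings with an estimated correlation, of those of heptanal minus hexanal with the scan batch as a block, and of those within each scan batch, were chosen after the results were seen. The third control set stood apart, where NTS, MAGEA6 and ATL1 differed from controls 1 and 2 by -2.80, -2.56 and -2.16 log2, and nonanal lay at -2.93, -2.63 and -2.13 against the mean of the other aldehydes. A slide effect is argued against, since over the 6054 genes that differ between control sets, control 3 minus control 1 had r = 0.704 with nonanal minus octanal, which shared a slide in the second scan batch. The first arrays of control 3 and nonanal shared a slide and a scanner of their own, so the first batch was no test of it. Separate cultures of the third control set are consistent with the 85% of these genes on which nonanal and control 3 differed from the rest with matching signs, and why the cultures would differ was not tested.

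Of 14 leukocyte markers 2 were called higher with hexanal, CD3E (1.87) and CSF1R (1.1). The list passed with the preset correlation but not with an estimated correlation (adjusted p = 0.161), and did so for pentanal (median 0.57, adjusted p = 0.0313 and 0.286) and nonanal (0.59, 0.013 and 0.216) too. Brightness alone is argued against, since the list median of 0.85 lay at percentile 100, rounded, of 10000 random lists of genes of the same brightness (median 0.17). The random genes were drawn independently, so correlation between the members of the list is not allowed for. With quantile normalization the list median was 0.40. Leukocyte RNA cannot be told apart from a change in A549 cells, with 10 of 14 markers well above background on every hexanal array, all of which except CD2 were so on every array of control 1 too. The transcripts named beforehand as abundant in leukocytes, PTPRC (0.47), CORO1A (0.89) and CD52 (1.35), were not called with hexanal. CD52 was well above background on 2 hexanal arrays and on 0 of control 1. CD2 (1.16), CD3D (0.80), CD14 (0.15), TYROBP (0.15), CD68 (0.10) and FCER1G (0.37) were not called either.

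Dim genes rose with most aldehydes. The genes in the lowest 10% of signal had median log2 changes of -0.020 for propanal, 0.58 for butanal, 0.55 for pentanal, 0.63 for hexanal, 0.57 for heptanal, 0.34 for octanal and 0.60 for nonanal, against 0.075, 0.21, 0.043, 0.049, -0.12, -0.073 and -0.0093 in the highest 10%, in the same order. In the first scan batch the lowest 10% had 0.43, 0.46, 0.25, 0.14, 0.16, 0.30 and 0.39, in that order. In the second batch they had -0.16, 0.92, 0.74, 0.83, 0.77, 0.35 and 0.74, so the propanal value averages opposite signs. There propanal shared a slide with control 3, while the other aldehydes lay on slides without a control. A slide effect on dim genes cannot be told apart from an effect of the aldehydes. Between scan batches 4 of the 7 aldehydes of the first batch were most correlated with themselves in the second, and 3 of the second with themselves in the first.

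The 6 arrays of a comparison make 10 splits, the real one included, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes. The real count and the highest of the other splits were 4875 against 0 for propanal, 3755 against 0 for pentanal, 1350 against 11 for hexanal, 1944 against 1 for heptanal, 1879 against 0 for octanal, 251 against 10 for nonanal, 2207 against 0 for hexanal minus pentanal and 4 against 0 for octanal minus heptanal. Of 100 regroupings within the control sets, the real one included, 1 was as large for the mean of 7 (6508 genes against at most 1964). The same held for nonanal minus octanal (1381 against 1), the trend to nonanal (4610 against 1993) and the genes shared by all 7 (4 against 0). It held for the list tests (82 against 63, or 30 against 2 with an estimated correlation) and the control sets (6054 against 4693, in a regrouping that kept the arrays of control 3 together). For heptanal minus hexanal 2 were as large, the real one with 960 and 1 with 1300, which put all 3 first-batch arrays of the second control set in 1 group. The next highest was 498. The share was 2 in 100. With the scan batch as a block in every regrouping the real one gave 2879 and the highest other 425, while with the median shift the real one gave 1. Shares of 1 or 2 in 100 argue against a random assignment of arrays to groups. They do not exclude a slide effect, since replicates 2 and 3 of a group lay on 1 slide and regroupings part them. The same goes for technical replicates of 1 culture.

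Groupings within each control set and each scan batch, in which every group kept its arrays per batch, were drawn as well (100 with the real one, or all 90 for the control sets). In each the real one alone was as large. This argues against a random assignment of arrays within a batch, and again not against a slide effect. The real count and the highest other were 6508 against 609 genes for the mean of 7, 960 against 39 for heptanal minus hexanal, 1381 against 27 for nonanal minus octanal, 4610 against 1248 for the trend to nonanal and 4 against 0 for the genes shared by all 7. They were 82 against 72 for the list tests, where the median of the other groupings was 46, 30 against 16 with an estimated correlation and 6054 against 3955 for the control sets.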
